A study of Homo sapiens with 14 samples.

How the data were processed

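Expression was measured in LNCaP cells, a human prostate cancer cell line, on a NimbleGen Homo sapiens expression array with 1 colour. Total RNA was taken after 24 h with DMSO vehicle (7 arrays), CG-1521 at 7.5 µM (4 arrays) or trichostatin A (TSA) at 5 µM (3 arrays). The labels call the arrays of each group biological replicates and give neither slide nor scan. The submitters' processing notes name RMA, with no version and no settings.

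The raw table holds the deposited probe intensity of 380811 probes on each of the 14 arrays, on a linear scale. A background correction by the authors was assumed and was not tested. Per the values themselves, the authors had already quantile-normalized these intensities, in 2 separate sets of arrays. Set A holds vehicle 1 to 4 and CG-1521 1 to 4, and set B holds vehicle 5 to 7 and TSA 1 to 3. Within a set the quantiles of the arrays differ by at most 0.063 (log2), against a tolerance of 0.1. Between the sets they differ by up to 1.32 (log2). The median intensity is 100.14 on vehicle 1 and 135.56 on vehicle 5. The labels do not mention these sets. The deposited value table holds a ratio for each of 36846 targets, on a linear scale. The authors divided each target by its median over the 14 arrays, as its values show: 99.7% of the targets have a median within 0.01 of 1. Its targets are not tied to genes in the files used here, so only counts are taken from it. The column medians run from 0.973 on CG-1521 1 to 1.10 on TSA 1. The scale and the centring were found from the values. Sorted differences between arrays had a spread near that of the raw table (median slope 1.08 within a set and 1.12 between sets). Sorted values give a positive slope either way, so the direction of the ratio was assumed. The value table's counts of higher and lower targets rest on that assumption.

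From the deposited intensities, log2 values were taken, quantile-normalized over all 14 arrays and summarised by median polish for each of 35952 targets (median of 11 probes per target). No further background correction was made, since the values were taken as already corrected. A target was named through its accession in the reference gene table (14376 targets), through a current symbol (3673) or a single older symbol (2356). The name in the array file was kept for 5483 targets, 215 targets with an older symbol of several genes received none, and 9849 had no name in the file. This gave 25888 named targets of 21529 genes. A gene with several targets is represented by the target with the highest mean over the 14 arrays. A name kept from the array file was treated as a gene of its own, even where it may be another name of a listed gene. MDM2 and KLK3 (PSA) were not matched by name. Probes of large families of similar sequence (metallothioneins, histones, HLA genes, tubulins) can cross-hybridise.

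Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, Benjamini-Hochberg adjustment over the 35952 targets, threshold 0.05), with all 14 arrays in 1 fit. The design written before the data were examined had a mean per group and no further term. Its fallback for a table that was already processed was the deposited value table. Once the 2 sets were seen in the values, a term for the set was added because the sets had been normalized separately, and the probe table was kept because the value table names no genes. A first plan kept the fit as designed and put the set term beside it. This was turned around before any count of changed targets was seen. Both fits were then run together, and the choice was kept with both counts in view. In that run 64.7% of the targets differed between the vehicle arrays of the sets. The values reported are from the fit with the set term (10 residual degrees of freedom, 6.14 prior degrees of freedom). It compares CG-1521 with vehicle 1 to 4 and TSA with vehicle 5 to 7. CG-1521 against TSA is the difference between those responses. The counts from the fit as first designed are given beside them. Standard errors (SE) are those of the fit. No interval for counting error applies to array intensities, and the number of arrays limits the precision.

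Before the data were examined, 31 gene lists were fixed. They cover genes commonly reported to rise with HDAC inhibitors, androgen receptor targets, luminal prostate epithelium, DNA replication and G1/S, G2/M and mitosis, p53 targets, CDK inhibitors and pocket proteins, pro-apoptotic genes, anti-apoptotic genes, cholesterol synthesis, fatty acid synthesis, the unfolded protein and amino acid stress response, heat shock proteins, metallothioneins, histones outside the replication-coupled set, histone deacetylases and sirtuins, histone acetyltransferases and bromodomain readers, neuronal and neuroendocrine genes, basal epithelial markers, fibroblast and smooth muscle markers, leukocyte and endothelial markers, mesenchymal transition genes, cytosolic ribosomal proteins, ribosome biogenesis and MYC-linked genes, proteasome subunits, DNA repair by homologous recombination and the Fanconi pathway, interferon response and class I antigen presentation, glycolysis and hypoxia, lysosome and autophagy, polyamine genes, and tubulins and actin regulators. The lists share members: 12 of the 22 HDAC inhibitor genes and 10 of the 34 p53 targets are in another list. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 31 lists. The test was repeated with a correlation estimated for each list and with limma's fry. Camera asks whether a list shifts relative to the other genes, and fry asks whether its genes move on balance one way. Members counted as risen or fallen passed the threshold over all targets. Counts "adjusted over the list alone" are given beside them.

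The genes named follow a rule written before the data were examined, with part 1 adapted to the sets afterwards. Part 1 took, per comparison, the 8 largest rises and the 8 largest falls among called genes in which every array of one group lies beyond every array of the other. As written, this meant all vehicle arrays. After the sets were seen, each drug was held against the vehicle arrays of its own set. For CG-1521 against TSA, each array's distance from its own vehicle mean was used. Part 2 took up to 3 called members of each gene list with the smallest adjusted p. Part 3 was a fixed group of 19 genes, 17 of which were matched, given whatever their values. The rule took 65 genes for CG-1521, 101 for TSA and 83 for the comparison of the 2 drugs. Parts 1 and 3 are given in full, apart from some genes of the rule that are not reported here. Of the genes that only part 2 took, the text gives some of those whose call held each time 1 array was left out: 15 of 33 genes for CG-1521, 49 of 70 for TSA and 14 of 51 for CG-1521 against TSA. Both the restriction and the choice within it were made after the values were seen. For each drug against vehicle, no fit without an array of the other drug was counted. Under the restriction, 17 of 33 such genes for CG-1521, 12 of 70 for TSA and 18 of 51 for CG-1521 against TSA lost their call without some array and are not named with a value for that comparison. The counts of list members cover all measured members.

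Alternatives fixed before the data were examined were cyclic loess and median centring in place of quantile normalization, the mean of the probes in place of median polish, the deposited value table, no dim targets, no set term, only the groups compared, a variance trend with robust estimates, array weights, the replicate number as a block, a stricter threshold, a fold threshold, other list tests, the mean over a gene's targets, and leaving out each array. The alternatives chosen after seeing the data were 16 or 50 added to the intensities, median polish within each set, and a covariate for a gradient between arrays. The fit was tested on simulated data for the 35952 targets. For CG-1521 against vehicle it called 92% of genes changed 2-fold and 100% of genes changed 4-fold. For TSA the shares were 80% and 100%. For CG-1521 against TSA they were 41% and 100% with the change placed in the CG-1521 arrays, and 36% and 97% with it placed in the TSA arrays. On simulated arrays with no change it made 0 calls in each comparison. The simulated arrays had no gradient. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and data.table (version 1.17.8).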

Results

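The transcripts of LNCaP prostate cancer cells were measured after 24 h with vehicle (n = 7 arrays), with CG-1521 at 7.5 µM (n = 4), which the labels call a histone deacetylase (HDAC) inhibitor, and with trichostatin A (TSA) at 5 µM (n = 3), an HDAC inhibitor. Each array holds 380811 probes, summarised here as 35952 targets. The arrays form 2 sets that were normalized separately. Set A holds vehicle 1 to 4 with the CG-1521 arrays, and set B holds vehicle 5 to 7 with the TSA arrays. Within a group and set, the target levels of any pair of arrays correlated across targets at 0.9417 or more (lowest for TSA 2 with TSA 3). Changes are log2 fold changes with their SE from limma, and p-values are adjusted.

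Which transcripts CG-1521 changes was asked against vehicle 1 to 4. After CG-1521, single stress genes and the CDK inhibitor gene CDKN1A rose, p53 targets shifted up as a list and genes of G2/M and mitosis shifted down. Both lists were called at the preset correlation and not with an estimated one (adjusted p = 0.0717 for each). HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose by 2.43 (SE 0.20, adjusted p = 2.06e-05), from 7.86 ± 0.41 (SD, n = 4) to 10.28 ± 0.38 (SD, n = 4). The stress-induced transcription factor ATF3 rose by 2.06 (SE 0.23, adjusted p = 0.000173). GADD45A, a gene induced by DNA damage, rose by 1.94 (SE 0.22, adjusted p = 0.000173). CDKN1A, which encodes the CDK inhibitor p21, rose by 1.63 (SE 0.23, adjusted p = 0.0013), from 10.82 ± 0.32 to 12.45 ± 0.16 (SD, n = 4 each). CCNB1, which encodes cyclin B1, fell by 2.16 (SE 0.24, adjusted p = 0.000173), from 9.59 ± 0.52 to 7.43 ± 0.45 (SD, n = 4 each).

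The other genes among the 8 largest rises were the target named TLS/CHOP in the array file (2.10), which belongs to a fusion transcript that shares sequence with DDIT3, DKFZp686G03223 (2.02), ZNF554 (2.00), CEL (1.95) and SERPINB5 (1.88), with adjusted p-values from 1.72e-05 to 0.00247. The 8 largest falls were CCNB1, CDC20 (-2.07), AURKA (-1.85), KIF20A (-1.81), FAM72D (-1.77), PLK1 (-1.75), MGC57827 (-1.75) and FAM83D (-1.68), with adjusted p-values from 1.72e-05 to 0.00203. CDC20, AURKA, KIF20A and PLK1 encode regulators of chromosome segregation and cell division. In each of these genes, all 4 CG-1521 arrays lay beyond all 4 vehicle arrays of the set, which was a condition of the rule that chose them. PLK1 (adjusted p = 0.00918) and MGC57827 (adjusted p = 0.0177) kept their call in the fit without the set term, and the other 6 falls did not, with adjusted p-values from 0.056 (CDC20) to 0.797 (FAM72D).

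**Figure D1:**
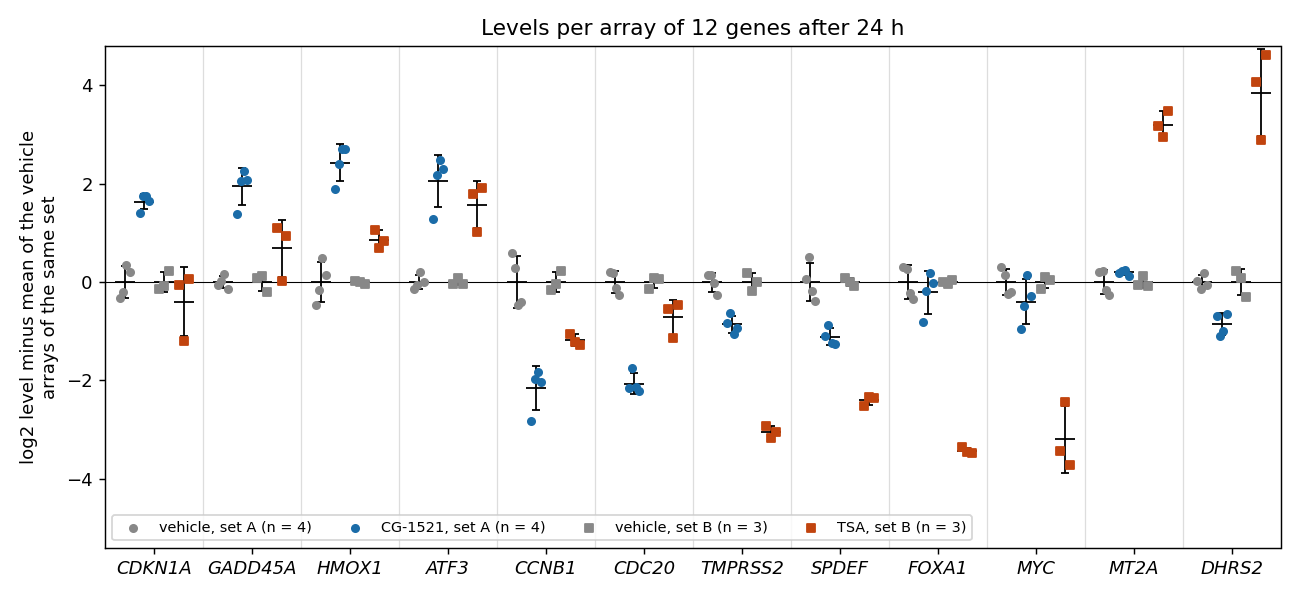
Log2 level of 12 genes on each array, minus the mean of the vehicle arrays of the same set. Points are arrays (circles for set A, squares for set B), and bars give the mean and the SD. The 4 CG-1521 arrays lie above vehicle for HMOX1 (mean change 2.43) and below it for CCNB1 (mean change -2.16), and the 3 TSA arrays lie below vehicle for FOXA1 (mean change -3.43) and above it for MT2A (mean change 3.20).

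Of the 47 measured genes of G2/M and mitosis, 28 fell with CG-1521 and 0 rose (41 fell adjusted over the list alone), with a median change of -0.80 (camera adjusted p = 5.7e-49, and adjusted p = 0.0717 with an estimated correlation). Of the 30 p53 targets, 9 rose and 0 fell (16 rose adjusted over the list alone), with a median change of 0.43 (camera adjusted p = 1.01e-12, and adjusted p = 0.0717 with an estimated correlation). TP53I3 rose by 1.21, FDXR by 0.89 and BAX, which encodes a pro-apoptotic protein, by 0.70 (adjusted p = 0.000329, 0.000919 and 0.00744). Of the 24 genes of glycolysis and hypoxia, 7 rose and 0 fell (10 rose adjusted over the list alone), among them ALDOC (1.33), BNIP3 (1.15) and PFKP (0.99), with a median of 0.26 (camera adjusted p = 8.72e-08, and adjusted p = 0.271 with an estimated correlation).

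Androgen receptor targets had a median change of -0.26: 5 of 25 fell and 0 rose (9 fell adjusted over the list alone), including the protease TMPRSS2 (-0.86, SE 0.14, adjusted p = 0.00317) and the receptor chaperone FKBP5 (-1.18, SE 0.19, adjusted p = 0.00377). The list's camera adjusted p was 8.72e-08, and the adjusted p was 0.271 with an estimated correlation. KLK2 did not pass (-0.43, adjusted p = 0.282). Of 20 luminal prostate genes, SPDEF fell (-1.11, adjusted p = 0.00157) and the other 19 did not pass; the list had a median of 0.03 and a mean of -0.04 (camera adjusted p = 0.581), and the median turned to -0.01 with cyclic loess. Ribosome biogenesis and MYC-linked genes had a median of -0.44 (3 of 25 fell, 13 adjusted over the list alone; camera adjusted p = 1.91e-10, and adjusted p = 0.271 with an estimated correlation). The spermidine synthase gene SRM fell by 0.62 (adjusted p = 0.00808). The ribosome biogenesis list, fitted with no set term, had a median of -0.02 (adjusted p = 0.837) and SRM changed by -0.33 (adjusted p = 0.818). In the same fit androgen receptor targets (adjusted p = 0.173), TMPRSS2 (0.683), FKBP5 (0.914) and SPDEF (0.235) lost their calls. Of the 17 lists called with CG-1521, 3 kept the call in that fit: G2/M, p53 targets and glycolysis. In the reported fit MYC did not pass (-0.40, adjusted p = 0.441).

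Further lists were called lower by camera at the preset correlation with CG-1521. Genes of DNA replication and G1/S had a median of -0.34 (2 of 45 fell, 9 adjusted over the list alone; camera adjusted p = 8.89e-10), cholesterol synthesis -0.30 (3 of 23 fell, adjusted p = 1.17e-06), histones outside the replication-coupled set -0.22 (3 of 15 fell, adjusted p = 0.000669), DNA repair genes -0.21 (0 of 30 passed, adjusted p = 0.00102), polyamine genes -0.34 (1 of 9 fell, adjusted p = 0.0126), histone acetyltransferases and bromodomain readers -0.07 (0 of 15 passed, adjusted p = 0.0126), fatty acid synthesis -0.26 (0 of 15 passed, adjusted p = 0.0175) and heat shock proteins -0.28 (1 of 18 rose, adjusted p = 0.044). Without CG-1521 1 the median of the polyamine genes was -0.03 (adjusted p = 0.0866), and fatty acid synthesis lost its call (0.359, and 0.0626 with the mean of the probes). Heat shock proteins lost theirs with cyclic loess (0.0524), the mean of the probes (0.134) or median polish within each set (0.0681), and without vehicle 1 (0.127), vehicle 2 (0.107), CG-1521 1 (0.189) or CG-1521 4 (0.0519). With a covariate for the gradient between arrays, the histone (0.131), DNA repair (0.11), polyamine (0.312), acetyltransferase (0.238), fatty acid (0.522) and heat shock (0.575) lists were not called. With an estimated correlation the adjusted p of these lists lay between 0.377 (cholesterol synthesis, histone acetyltransferases) and 0.645 (heat shock proteins).

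The genes commonly reported to rise with HDAC inhibitors did not shift as a list with CG-1521 (median 0.07, camera adjusted p = 0.491): 3 of 20 rose, 2 fell and 15 did not pass. Those that rose were CDKN1A, GSN (0.99, adjusted p = 0.000797), which encodes the actin-severing protein gelsolin, and TUBB3 (1.16, adjusted p = 0.00378). The list of HDACs and sirtuins did not shift (median 0.06, 0 of 16 passed, adjusted p = 0.778), and HDAC1 (-0.06), HDAC2 (-0.38) and HDAC3 (-0.24) did not pass (adjusted p = 0.853, 0.305 and 0.443).

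Lists that were not called with CG-1521 held single genes that rose. Among genes of the unfolded protein and amino acid stress response, DDIT3, which encodes the transcription factor CHOP, rose by 1.84 (adjusted p = 0.000218) and CHAC1 by 0.89 (adjusted p = 0.00149); 5 of 26 rose, while the list had a median of -0.05 and a mean of 0.14 (camera adjusted p = 0.179). Without CG-1521 1 that list had a median of 0.15 and was called (adjusted p = 0.000247), as with the gradient covariate (median 0.05, adjusted p = 0.00551). Among tubulins and actin regulators, 4 of 25 rose, among them TMSB4X (0.94, adjusted p = 0.00729), with a median of -0.11 and a mean of 0.11 (adjusted p = 0.778). Of 25 interferon and antigen presentation genes, 3 rose, with a list median of 0.13 (adjusted p = 0.147, and 0.0332 without vehicle 3 or 0.0435 without CG-1521 2). The lists of CDK inhibitors (median 0.08, mean 0.10, while camera gave the direction down; adjusted p = 0.996), pro-apoptotic genes (0.06, adjusted p = 0.119), anti-apoptotic genes (-0.04, adjusted p = 0.416), metallothioneins (0.08, adjusted p = 0.778), ribosomal proteins (-0.08, adjusted p = 0.0622), proteasome subunits (-0.00489, adjusted p = 0.699) and lysosome and autophagy (0.10, adjusted p = 0.0723) were not called. Some of these were called in other fits. Pro-apoptotic genes were called without vehicle 1 (median 0.13, adjusted p = 0.015), vehicle 2 (0.0374) or CG-1521 1 (median 0.15, adjusted p = 0.00269) and with the gradient covariate (8.65e-05). Lysosome and autophagy genes were called without vehicle 1 (0.0157), vehicle 2 (0.0269) or CG-1521 1 (0.000808), with 16 (0.0439) or 50 (0.0247) added to the intensities, with the mean of the probes (0.0442), with median polish within each set (0.0313) and with the gradient covariate (2.85e-05). Ribosomal proteins were called with median centring (0.0466) and without CG-1521 2 (0.0335), and proteasome subunits with the gradient covariate (0.000129).

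Of 5 lists of markers of other cell types, 4 were called upward by camera with CG-1521, and 3 of these calls depend on single arrays and on the processing. Neuronal and neuroendocrine genes had a median of 0.15 (3 of 40 rose; camera adjusted p = 0.00284), among them the neuron-specific enolase gene ENO2 (1.46, adjusted p = 0.0015), which also codes for a glycolytic enzyme. Fibroblast and smooth muscle markers had a median of 0.21 (0 of 19 passed), leukocyte and endothelial markers 0.18 (0 of 15 passed) and mesenchymal transition genes 0.18 (1 of 18 rose, FN1 by 1.07, adjusted p = 0.00193), with camera adjusted p = 0.0256 for each. Basal epithelial markers had a median of 0.13 (0 of 10 passed, adjusted p = 0.199). Without CG-1521 1 the medians of the fibroblast, leukocyte and mesenchymal lists were 0.07, 0.13 and 0.08 and none was called (adjusted p = 0.289, 0.177 and 0.191). The fibroblast call was also lost without vehicle 1 (0.0895) and with 16 (0.0616) or 50 (0.0639) added to the intensities. The leukocyte call was lost without vehicle 1 (0.0599) or 2 (0.0639), with 50 added (0.0707) and with median polish within each set (0.0659), and the mesenchymal call with the mean of the probes (0.0975) or median polish within each set (0.0725). With the gradient covariate none of the 4 was called (adjusted p = 0.204 for neuronal genes, 0.575 for fibroblast, 0.471 for leukocyte and 0.409 for mesenchymal genes). None of these 5 lists was called with an estimated correlation, where the adjusted p lay between 0.406 (neuronal genes) and 0.645 (basal markers).

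In limma's test, CG-1521 changed 673 targets, of which 361 were higher and 312 lower, and 144 changed at least 2-fold (78 higher, 66 lower). At an unadjusted p under 0.05, 6025 targets differed. Without the set term, as first designed, 168 targets passed (153 higher, 15 lower). With cyclic loess 713 passed (306 higher, 407 lower, so 42.9% higher against 53.6%). The count was 283 without vehicle 1, 262 without vehicle 2, 436 without vehicle 5, 444 without CG-1521 2, 419 without CG-1521 3 and 279 without CG-1521 4. CCND1, which encodes cyclin D1, fell by 0.83 (adjusted p = 0.029) but lost the call without vehicle 1 (0.119), vehicle 2 (0.122), CG-1521 1 (0.0608), CG-1521 2 (0.0786) or CG-1521 4 (0.0594). The thymidylate synthase gene TYMS fell by 0.73 (adjusted p = 0.0475) but lost the call without vehicle 1 (0.174), 2 (0.188), 3 (0.0598), 5 (0.073), 6 (0.0701) or 7 (0.0698), without CG-1521 1 (0.1), 3 (0.0816) or 4 (0.127), and with median centring (0.0538). ACTB (-0.15, adjusted p = 0.68) and GAPDH (0.21, adjusted p = 0.676) did not pass.

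Which transcripts TSA changes was asked against vehicle 5 to 7. After TSA, metallothionein genes rose, and genes of the luminal prostate lineage, androgen receptor targets and genes of ribosomes and protein turnover fell. Falls went beyond these lists: of the 1641 targets changed at least 2-fold, 1544 were lower, and ACTB and GAPDH fell as well. ACTB (-0.813, -1.6 and -0.631 on TSA 1 to 3) and GAPDH (-0.821, -1.83 and -0.217) fell most on TSA 2. That array lies farthest along the gradient between arrays. MYC fell least on it (-2.44), and FOXA1 fell alike on the 3 TSA arrays (-3.36 to -3.47). How much of the falls comes with the gradient was not settled. FOXA1, which encodes a pioneer factor of the androgen receptor, fell by 3.43 (SE 0.22, adjusted p = 2.23e-07). MYC fell by 3.20 (SE 0.29, adjusted p = 3.56e-06). The metallothionein gene MT2A rose by 3.20 (SE 0.17, adjusted p = 1.76e-08), from 11.78 ± 0.11 to 14.98 ± 0.27 (SD, n = 3 each). The dehydrogenase gene DHRS2 rose by 3.85 (SE 0.30, adjusted p = 8.06e-07).

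The other genes among the 8 largest rises were MIR7-3HG (3.06), MT1X (2.99), MT1G (2.75), TUBA1A (2.66), a further target named metallothionein in the array file (2.64) and the phosphatase gene DUSP1 (2.40), with adjusted p-values from 1.36e-07 to 0.00504. The other large falls were a target named c-myc in the array file (-3.50), DKFZp451D112 (-3.47), FOLH1 (-3.22), which encodes prostate-specific membrane antigen, NUCKS1 (-3.18) and the sorbitol dehydrogenase gene SORD (-3.13), with adjusted p-values from 2.23e-07 to 5.01e-06. All 3 TSA arrays lay beyond all 3 vehicle arrays of the set in each of these genes, again a condition of the rule that chose them.

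Of 25 androgen receptor targets, 14 fell and 1 rose (16 fell and 1 rose adjusted over the list alone), with a median change of -1.26 (camera adjusted p = 5.08e-13, and adjusted p = 0.0617 with an estimated correlation). TMPRSS2 fell by 3.05 (SE 0.16, adjusted p = 1.76e-08) and SLC45A3 by 2.53 (SE 0.17, adjusted p = 2.44e-07). KLK2 did not pass (-0.17, adjusted p = 0.629). Of 20 luminal prostate genes, 12 fell and 1 rose (12 and 2 adjusted over the list alone), among them SPDEF (-2.41, adjusted p = 8.06e-07), with a median of -1.04 (camera adjusted p = 3.82e-10, and adjusted p = 0.0617 with an estimated correlation).

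Of 8 metallothionein genes, 7 rose and 0 fell (7 rose adjusted over the list alone), with a median of 1.56 (camera adjusted p = 3.82e-10, and adjusted p = 0.0617 with an estimated correlation). Of the 20 genes commonly reported to rise with HDAC inhibitors, 10 rose and 0 fell, with a median of 0.74 (camera adjusted p = 3.62e-07, and adjusted p = 0.0617 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell. Those that rose included DHRS2, MT2A, MT1X, GSN (0.79, SE 0.15, adjusted p = 0.00247) and the CDK inhibitor gene CDKN2D (0.94, adjusted p = 0.00295). CDKN1A did not pass (-0.40, SE 0.27, adjusted p = 0.333); without TSA 2 its change was 0.00555.

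Lists of genes of protein synthesis and turnover were called lower with TSA at the preset correlation, and none was with an estimated one. Of 50 cytosolic ribosomal proteins, 31 fell and 0 rose (44 fell adjusted over the list alone), among them RPL27 (-1.25), with a median of -0.87 (camera adjusted p = 1.25e-20, and adjusted p = 0.275 with an estimated correlation). Of 25 ribosome biogenesis and MYC-linked genes, 15 fell and 1 rose, with a median of -0.89 (camera adjusted p = 1.95e-13, and adjusted p = 0.133 with an estimated correlation); the nucleophosmin gene NPM1 fell by 2.73 and SRM by 1.11. Of 31 proteasome subunits, 18 fell and 0 rose, among them PSMA4 (-1.76), PSMB5 (-1.49) and PSMB2 (-1.07), with a median of -0.75 (camera adjusted p = 1.41e-12, and adjusted p = 0.29 with an estimated correlation). Of 26 genes of the unfolded protein and amino acid stress response, 14 fell and 1 rose, with a median of -0.71 (camera adjusted p = 1.29e-09, and adjusted p = 0.193 with an estimated correlation); XBP1 fell by 2.51, ATF4 fell by 2.35 and TRIB3 fell by 1.24. Of 18 heat shock proteins, 6 fell and 1 rose, with a median of -0.50 (camera adjusted p = 0.00561, adjusted p = 0.42 with an estimated correlation, 0.0783 with cyclic loess, 0.0677 without TSA 2 and 0.159 with the gradient covariate); HSPE1 fell by 2.11, HSPD1 by 1.55 and HSP90AB1 by 1.45.

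Lists of metabolic and cell cycle genes were also called lower with TSA at the preset correlation, though most members of the cholesterol, G2/M and DNA replication lists did not pass. Of 15 fatty acid synthesis genes, 8 fell and 1 rose (median -0.74, camera adjusted p = 1.82e-06, and adjusted p = 0.275 with an estimated correlation), among them SCD (-1.90), ACACA (-1.64) and FADS2 (-1.15). Of 23 genes of cholesterol synthesis, 6 fell and 1 rose (median -0.28, camera adjusted p = 0.00594, and adjusted p = 0.44 with an estimated correlation; without TSA 2 the median was -0.04 with adjusted p = 0.077, and the gradient covariate gave 0.151): EBP fell by 1.20, and INSIG1, which restrains sterol synthesis, rose by 1.36. Of 47 G2/M genes, 12 fell and 0 rose (median -0.36, camera adjusted p = 5.86e-08, and adjusted p = 0.352 with an estimated correlation), among them CKS1B (-1.78), CDK1 (-1.70) and UBE2C (-1.36). CCNB1 fell by 1.19 (adjusted p = 0.00864), a call lost with 50 added to the intensities (adjusted p = 0.0666). Of 45 genes of DNA replication and G1/S, 11 fell and 1 rose (median -0.21, camera adjusted p = 2.31e-05, adjusted p = 0.44 with an estimated correlation, and median 0.05 with adjusted p = 0.159 with the gradient covariate): TYMS fell by 2.48, RRM2 by 1.67 and UHRF1 by 1.33. CCND1 fell by 2.59 (adjusted p = 1.23e-06).

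Among glycolysis and hypoxia genes 9 of 24 fell and 1 rose with TSA (median -0.12, camera adjusted p = 0.000732, 0.352 with an estimated correlation and 0.0529 with the gradient covariate), among them LDHA (-2.07), ENO1 (-1.47) and PGAM1 (-1.36). Among tubulins and actin regulators 8 of 25 fell, such as TUBB (-1.80) and TUBA1B (-1.46), and 5 rose, such as TUBA1A and TUBB2B (1.71). The list had a median of -0.11 (camera adjusted p = 0.0405, 0.352 with an estimated correlation, 0.483 with cyclic loess, 0.0559 with median centring, 0.0605 with the mean of the probes and 0.108 without TSA 2). Polyamine genes had a median of -0.63 (4 of 9 fell and 1 rose, camera adjusted p = 0.00509, 0.28 with an estimated correlation, 0.0595 with cyclic loess and 0.0638 with the gradient covariate), with falls of SMS (-1.82) and AMD1 (-1.70). Histones outside the replication-coupled set had a median of -0.17 (5 of 15 fell, camera adjusted p = 0.0188, adjusted p = 0.447 with an estimated correlation and adjusted p = 0.114 with cyclic loess). That median turned to 0.10 without TSA 2 (adjusted p = 0.0989) and to 0.25 with the gradient covariate (adjusted p = 0.662), while camera's direction stayed down. Its members include falls of H2AZ1 (-1.88), H3-3A (-1.42) and MACROH2A1 (-1.39). Histone acetyltransferases and bromodomain readers had a median of -0.22 (5 of 15 fell, camera adjusted p = 0.0136, adjusted p = 0.285 with an estimated correlation, and median 0.07 with adjusted p = 0.23 with the gradient covariate), with falls of KAT2A (-1.03) and BRD2 (-0.86). Anti-apoptotic genes had a median of -0.28 (4 of 12 fell, camera adjusted p = 0.023, 0.335 with an estimated correlation, 0.0641 without vehicle 7, 0.0573 without TSA 2 and 0.434 with the gradient covariate), with a fall of BCL2L1 (-1.02).

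The p53 targets did not shift as a list with TSA: 4 of 30 fell and 0 rose, with a median of 0.05, a mean of -0.17 and camera adjusted p = 0.193, and the median turned to -0.12 with cyclic loess. PERP fell by 2.41, RPS27L by 2.19 and AEN by 1.24 (adjusted p = 0.000141, 2.99e-05 and 0.00181). Not called either were CDK inhibitors and pocket proteins (median 0.02, mean -0.07, -0.14 with cyclic loess, adjusted p = 0.878), of which RBL2 fell (-1.70), pro-apoptotic genes (median 0.05, mean -0.00298, -0.03 with cyclic loess, adjusted p = 0.673), DNA repair genes (median 0.01, mean -0.12, -0.14 with cyclic loess, adjusted p = 0.161), interferon and antigen presentation genes (0.07, adjusted p = 0.923), lysosome and autophagy (0.05, -0.03 with cyclic loess, adjusted p = 0.878) and HDACs and sirtuins (median -0.03, mean 0.07, 0.02 with median centring, adjusted p = 0.923). In the last list SIRT4 rose by 1.04 (adjusted p = 0.00202), HDAC1 did not pass (-0.26, adjusted p = 0.305), and HDAC2 (-0.65, adjusted p = 0.0507) and HDAC3 (0.54, adjusted p = 0.0548) lay just outside the threshold. HDAC2 passed with median centring (0.0434), with cyclic loess (0.0288) and without vehicle 1 (0.0458) or 4 (0.0491), and HDAC3 passed with median centring (0.0356) and without vehicle 1 (0.0475) or TSA 2 (0.0174).

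Of the 5 lists of markers of other cell types, 3 were called upward with TSA. Neuronal and neuroendocrine genes had a median of 0.29 (7 of 40 rose, camera adjusted p = 0.000695), among them NEFH (1.39), SYT11 (1.17) and STMN4 (1.06). Mesenchymal transition genes had a median of 0.26 (1 of 18 rose, adjusted p = 0.0257, and 0.123 without TSA 3 or 0.362 with the gradient covariate). Leukocyte and endothelial markers had a median of 0.26 (1 of 15 rose, camera adjusted p = 0.0424). The gene that rose was HBA1 (1.71), a hemoglobin gene that the list also holds. The other 14, with all its leukocyte and endothelial markers, did not pass. The leukocyte call was lost with median centring (0.0557), with median polish within each set (0.0507), with the gradient covariate (0.621) and without vehicle 5 (0.0678), vehicle 6 (0.0723), TSA 1 (0.0935) or TSA 2 (0.101). Basal markers (0.32, 1 of 10 rose, adjusted p = 0.107, and 0.0312 with the mean of the probes) and fibroblast and smooth muscle markers (0.24, 1 of 19 rose, adjusted p = 0.119) were not called. With an estimated correlation none of these 5 lists was called, with adjusted p from 0.285 (neuronal genes) to 0.515 (fibroblast markers). Of the 22 lists called with TSA, 11 lost the call with the gradient covariate, and not every such loss is printed. A list given without a value for that covariate may therefore have lost its call too.

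In limma's test, TSA changed 4766 targets, of which 1711 were higher and 3055 lower; 1641 changed at least 2-fold (97 higher, 1544 lower). The fit without the set term called 18180 (11655 higher, 6525 lower). With cyclic loess the count was 3643 (669 higher, 2974 lower, so 18.4% higher against 35.9%), and the median change of all targets was 0.02 against 0.14. The deposited value table, with the direction of its ratios assumed, gave 2883 (492 higher, 2391 lower, 17.1% higher). Median polish within each set gave 3890 (24% higher), and 50 added to the intensities 5363 (48.6% higher). The count was 2651 without vehicle 5, 2889 without vehicle 6 and 3108 without vehicle 7. ACTB fell by 1.02 (adjusted p = 0.00195) and GAPDH by 0.96 (adjusted p = 0.024). The GAPDH call was lost with cyclic loess (0.174) and without vehicle 5 (0.0713), 6 (0.0551) or 7 (0.0868) or TSA 2 (0.0563).

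**Figure D2:**
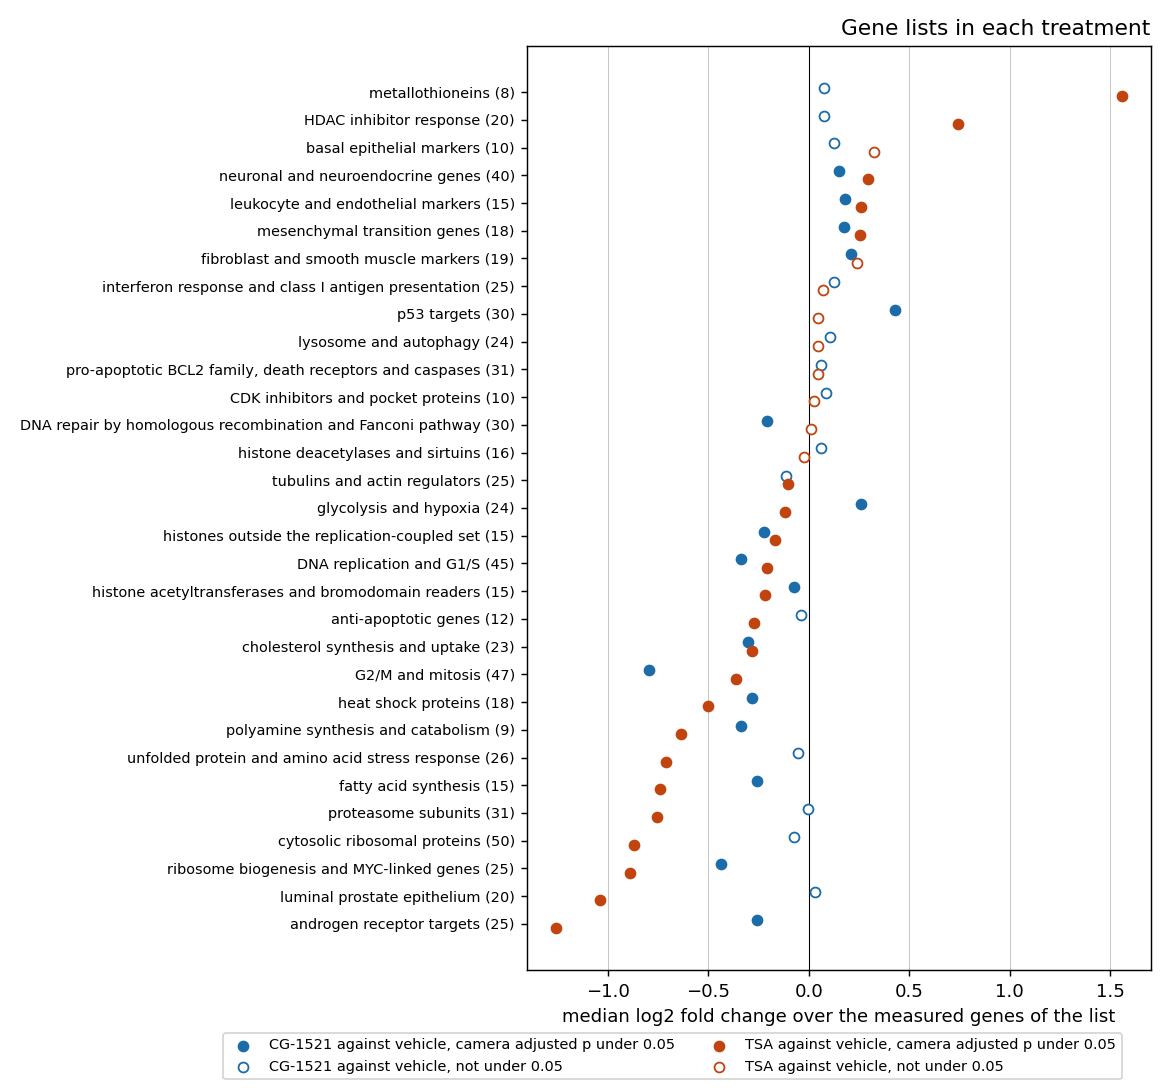
Median log2 fold change over the measured genes of each of 31 lists, with CG-1521 (blue) and TSA (red) against the vehicle arrays of the same set; the number of measured genes is in brackets. Filled points have a camera adjusted p under 0.05 at the preset correlation. The G2/M list lies at -0.80 with CG-1521 and -0.36 with TSA, and the metallothionein list at 0.08 and 1.56. Points within 0.1 of 0 can change sign with the normalization.

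The responses to the 2 drugs were then compared directly, as the difference between each drug's change against its own vehicle arrays; the doses differ (7.5 µM and 5 µM). FOXA1 was higher after CG-1521 than after TSA by 3.22 (SE 0.30, adjusted p = 2.8e-05). CDKN1A was higher by 2.03 (SE 0.36, adjusted p = 0.0036). MT2A was lower by a log2 difference of -3.0 (SE 0.22, adjusted p = 3.32e-06), and DHRS2 by -4.71 (SE 0.40, adjusted p = 1.49e-05). The other large positive differences were DKFZp451D112 (3.31), PRUNE2 (3.29), a target named kIAA0367 in the array file (3.23), FOLH1 (3.03), the target named c-myc (3.03) and the calcineurin gene PPP3CA (2.95), with adjusted p-values from 1.76e-06 to 0.000477. The PRUNE2 and kIAA0367 targets moved alike on the TSA arrays (-2.71, -2.65 and -3.34 against -2.68, -2.77 and -3.16). They may measure the same gene. The other large negative differences were MT1X (-3.34), MIR7-3HG (-3.07), MT1G (-2.77), the target named metallothionein (-2.52), OAT (-2.23) and the ornithine decarboxylase gene ODC1 (-1.89). ODC1 (adjusted p = 0.0158) lost the call without vehicle 6 (0.0524) and with the mean of the probes (0.0544).

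Metallothioneins were lower after CG-1521 than after TSA (median -1.63, 5 of 8 lower and 0 higher, camera adjusted p = 1.55e-12), the only list among the 31 that was also called with an estimated correlation (adjusted p = 0.0287). The p53 targets were higher after CG-1521 (median 0.59, 10 of 30 higher and 0 lower, 14 higher adjusted over the list alone, camera adjusted p = 9.8e-12, and adjusted p = 0.0666 with an estimated correlation), with PERP at 2.69 and RPS27L at 2.45. Luminal prostate genes (median 0.70, 7 of 20 higher, such as CLDN7 at 2.09; camera adjusted p = 7.43e-12) and androgen receptor targets (median 0.71, 9 of 25 higher and 1 lower, such as TMPRSS2 at 2.19 and SLC45A3 at 1.74; camera adjusted p = 2.55e-08) were higher after CG-1521. With an estimated correlation their adjusted p was 0.0666 and 0.131. The list of genes reported to rise with HDAC inhibitors was lower (median -0.41, 7 of 20 lower and 1 higher, camera adjusted p = 2.66e-06, and adjusted p = 0.0666 with an estimated correlation).

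The unfolded protein and amino acid stress genes were higher after CG-1521 than after TSA (median 0.89, 8 of 26 higher and 0 lower, camera adjusted p = 1.21e-14, and adjusted p = 0.0666 with an estimated correlation), with ATF4 at 2.63, XBP1 at 2.45 and TRIB3 at 1.79. Glycolysis and hypoxia genes were higher as well (median 0.79, 10 of 24 higher and 0 lower, camera adjusted p = 1.19e-12, and adjusted p = 0.0666 with an estimated correlation), with PGK1 at 1.99, GPI at 1.72 and PGAM1 at 1.63. PGK1, GPI and TRIB3 were each called in both treatments, higher with CG-1521 and lower with TSA. The G2/M list was lower after CG-1521 (median -0.46, 8 of 47 lower and 0 higher, camera adjusted p = 1.38e-08, and adjusted p = 0.411 with an estimated correlation), with BUB1 at -1.52, CDC20 at -1.35 and ANLN at -1.18; CCNB1 did not pass (-0.98, adjusted p = 0.189). The ANLN call was lost with the mean of the probes (adjusted p = 0.169). CDKN2D was lower by a difference of -1.40 (adjusted p = 0.00368).

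Ribosomal proteins (median 0.86, 5 of 50 higher, camera adjusted p = 3.89e-18), proteasome subunits (0.83, 5 of 31 higher, 8.41e-13), ribosome biogenesis and MYC-linked genes (0.49, 5 of 25 higher and 1 lower, 8.84e-05), fatty acid synthesis genes (0.43, 4 of 15 higher, 0.000203) and tubulins and actin regulators (0.34, 4 of 25 higher and 1 lower, 0.00241, which became 0.219 with cyclic loess) were also higher after CG-1521 by camera. With an estimated correlation the adjusted p of these 5 lists was 0.277, 0.334, 0.411, 0.398 and 0.225. MYC was higher by 2.80, CCND1 by 1.76 and TYMS by 1.76 (adjusted p = 0.00063, 0.00194 and 0.00158); the TYMS call was lost with 50 added to the intensities (0.0912). GSN (0.19, adjusted p = 0.749), KLK2 (-0.26, 0.781), HDAC1 (0.20, 0.769), HDAC2 (0.27, 0.741), HDAC3 (-0.78, 0.0848), ACTB (0.87, 0.0732) and GAPDH (1.16, 0.083) did not pass. HDAC3 passed without TSA 2 (0.0272), and ACTB (0.0154) and GAPDH (0.00414) passed without TSA 3. The other 18 lists were not called in this comparison, but some were in other fits. Heat shock proteins were called without vehicle 1 (0.0387), vehicle 2 (0.0478), CG-1521 1 (0.0366), TSA 1 (0.0431) or TSA 3 (0.019), with 50 added to the intensities (0.0309) and with the mean of the probes (0.0405). Polyamine genes were called without vehicle 1 (0.0462) or CG-1521 1 (0.0365) and with the mean of the probes (0.0405). Anti-apoptotic genes were called with no dim targets (0.0169), pro-apoptotic genes without CG-1521 1 (0.0314) and neuronal genes without vehicle 1 (0.0377).

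In limma's test of the difference, 1265 targets passed, of which 1041 were higher and 224 lower after CG-1521, and 922 differed at least 2-fold. The fit without the set term called 20564 (7704 higher, 12860 lower). The count was 679 without vehicle 5, 750 without vehicle 6, 804 without vehicle 7, 834 without CG-1521 2 and 831 without CG-1521 4, and it rose to 2343 without CG-1521 1 and 1915 without TSA 3. The calls against vehicle overlapped: 52 targets were higher with both drugs (17.2 would be for independent lists) and 118 lower with both (26.5), while 21 were higher with CG-1521 and lower with TSA (30.7) and 3 the opposite (14.8). The 170 targets called in the same direction became 53 without vehicle 2, 63 without vehicle 1, 69 without CG-1521 4 and 30 with no set term. The log2 fold changes of the 2 drugs correlated across targets at r = 0.422 (covariance 0.0559), with different vehicle arrays in each. Targets are not independent replicates. Different vehicle arrays do not remove the gradient between arrays. The TSA change correlated across targets at 0.454 with vehicle 3 to 4 minus vehicle 1 to 2. The r of 0.422 and the overlap therefore cannot be read as a shared drug response alone. With the gradient covariate 148 targets were called in the same direction, and r was not computed. Without the set term, where both drugs share all 7 vehicle arrays, r was -0.436 (covariance -0.0931), against 0.33 (covariance 0.0188) in 50 simulations of unchanged groups that share vehicle arrays, in which the calls overlapped at 0 targets.

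The vehicle arrays of set B differed from those of set A at 23273 of 35952 targets (13284 higher, 9989 lower), of which 6406 differed at least 2-fold, though both are vehicle-treated LNCaP cells. The arrays also differed within the vehicle group of set A. The first component of the vehicle arrays within their sets held 62.3% of that variance, and scores on it ran from -1.13 on vehicle 1 and -0.88 on vehicle 2 to -0.38 on vehicle 3 and -0.27 on vehicle 4. CG-1521 1 scored 0.08, apart from the other CG-1521 arrays (-0.41 to -0.66), and the TSA arrays scored from 0.80 to 1.04 against 0.47 to 0.49 for their vehicle arrays. The score was built from vehicle arrays that are also in the fit.

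**Figure D3:**
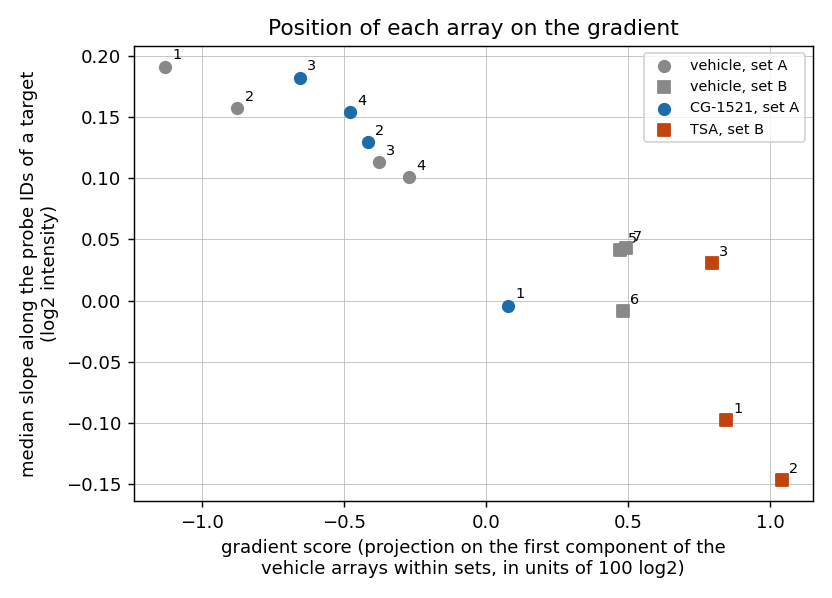
Gradient score of each array (x axis, in units of 100 log2) against the median slope of its probe levels along the probe IDs of a target (y axis, log2). Each point is an array with its replicate number. Vehicle 1 (score -1.13, slope 0.19) and TSA 2 (score 1.04, slope -0.15) lie at the ends.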

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

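All 6 values here come from a test for single arrays far from the others of their group, in groups of 4 arrays, over the genes given in the text. Of 150 groups tested, 6 held such an array, while chance alone gives about 7.5. No explanation is offered for them.

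On CG-1521 1, the log2 level of ANLN was 4.34 against 4.73 to 4.76 on the other CG-1521 arrays, and that of ATF4 was 12.3 against 12.8 to 12.9. On the same array DKFZp686G03223 stood at 8.06 against 8.65 to 8.72, and SLC45A3 at 9.60 against 10.1 to 10.2. On CG-1521 2, CDC20 stood at 8.70 against 8.24 to 8.31 on the others. On vehicle 2 of set A, DDIT3 stood at 6.60 against 7.26 to 7.38 on the other vehicle arrays of the set.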

How the results depend on the processing

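The numbers of called targets depend on the set term, on single arrays and on the threshold, and the cause of a change was not tested unless stated. Chosen after seeing the data were the set term itself, 16 or 50 added to the intensities, median polish within each set and the gradient covariate. Leaving out each array in turn gave 262 to 871 called targets for CG-1521 (673 with all arrays), 2651 to 4930 for TSA (4766), 679 to 2343 for CG-1521 against TSA (1265) and 53 to 244 targets called in the same direction with both drugs (170). For each drug against vehicle, no fit without an array of the other drug was counted. Without the set term, 168, 18180 and 20564 targets were called and 30 overlapped. By construction, vehicle arrays of the other set then enter each drug's contrast with vehicle, and CG-1521 against TSA uses no vehicle array, so that drug and set cannot be told apart in it. The deposited value table gave 487, 2883 and 697 targets within the sets (98 overlapped) and 66, 9243 and 18100 without the set term. Array weights gave 3175, 16722 and 10363 targets; they weighted TSA 1 at 6.22, TSA 2 at 0.213 and TSA 3 at 0.286, so that the TSA group rests mostly on 1 array. With only the groups compared, CG-1521 gave 414 targets, and CG-1521 against TSA gave 22768, where drug and set cannot be told apart. The gradient covariate gave 2623 targets for CG-1521 against TSA, including all 1265. At an adjusted p under 0.01, 222, 2304 and 533 targets passed, and with a 2-fold threshold as well 144 (CG-1521) and 1641 (TSA). The overlap was 261 with 16 added, 287 with 50 added and 283 with the mean of the probes. Cyclic loess, median centring, median polish within each set, no dim targets and the variance trend kept each count they were run on within 1.5 times. Of 171 gene values, 169 kept their direction and side of the threshold with cyclic loess, 168 with median centring, 168 with 50 added and 161 with the gradient covariate. The leave-one-out fits cannot be read as evidence for the genes named from the lists, since these were chosen for it. Of the 52 list results with a camera call, 51 lost it with an estimated correlation, 23 with fry, 6 with cyclic loess and 21 with the gradient covariate. Of the 17 called for CG-1521, 3 kept the call with no set term. Over all 3 comparisons, 23 gene values lost theirs in that fit with the direction kept. ANLN against TSA also lost its call there, with the direction turned (0.404, adjusted p = 0.436).

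The following changed sign, with a call on at least 1 side, first the lists in which camera's direction turned. Without the set term, the CG-1521 list medians were 0.0392 for DNA replication, 0.0288 for fatty acid synthesis, 0.183 for heat shock proteins, -0.102 for fibroblast markers, -0.0868 for leukocyte markers, 0.16 for ribosomal proteins, 0.529 for proteasome subunits and 0.172 for polyamine genes; against TSA they were 0.293 for G2/M, 0.82 for cholesterol synthesis and 0.243 for DNA repair. ANLN stood at 0.404 and GSN at -0.705 against TSA. With only the CG-1521 and TSA arrays, ANLN (0.404), CCNB1 (0.829), GSN (-0.705) and KLK2 (0.627) turned, again where drug and set cannot be told apart. With the gradient covariate, the proteasome list turned to 0.228 with CG-1521.

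In other lists with a call on at least 1 side the median turned while camera's direction did not. Without the set term these were, with CG-1521, histones (0.11), neuronal (-0.0509), mesenchymal (-0.0297), DNA repair (0.00946), unfolded protein (0.367) and tubulin genes (0.0819), with TSA, p53 targets (-0.27), pro-apoptotic (-0.281) and DNA repair genes (-0.277), and against TSA, DNA replication (0.845), histones (0.627) and acetyltransferases (0.596). With the gradient covariate they were unfolded protein genes with CG-1521 (0.0481) and, with TSA, histones (0.253), DNA replication (0.0546), acetyltransferases (0.0673) and anti-apoptotic genes (0.00297). Unfolded protein genes also turned without CG-1521 1 (0.151), and TSA histones without TSA 2 (0.0982).

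No pairing by replicate number was seen: deviations of vehicle and CG-1521 arrays of the same number correlated across targets at -0.616, 0.0462, -0.544 and -0.309. These deviations also hold the gradient between arrays, so they cannot exclude a pairing. With the number as a replicate block within set A, 16 targets were called for CG-1521. Without the set term the replicate block gave 115, 25729 and 22336 targets and an overlap of 69. In that blocked fit, lysosome genes with TSA had a median of -0.425, and against TSA the G2/M list stood at 0.374, cholesterol synthesis at 0.882 and DNA repair at 0.283. Medians alone turned in it for p53 targets (-0.459), pro-apoptotic (-0.506) and DNA repair genes (-0.582) with TSA, and for DNA replication (0.845), histones (0.614) and acetyltransferases (0.575) against TSA. Genes that turned in it were ANLN (0.395), CCNB1 (0.874), CDC20 (0.0174), GSN (-0.7) and KLK2 (0.746) against TSA, and INSIG1 (-0.158) with TSA. The numbers 1 to 3 of TSA recur in set A only, so this fit has no set term.

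Not run were a slide or scan block, since the files give neither, and normexp at either offset, since the intensities were taken as already corrected. No background correction is the setting reported, and vehicle arrays split 4 and 3 between the drugs are what the set term gives.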

Other observations

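Genes outside the rule for named genes, chosen after their values were seen, show where the drugs moved apart and where they moved together. The amino acid transporter gene SLC3A2 rose with CG-1521 (0.99, adjusted p = 0.00938) and fell with TSA (-1.68, adjusted p = 6.32e-05), a difference of 2.67 (adjusted p = 6.6e-05). The quinone reductase gene NQO1 rose by 0.85 with CG-1521 (adjusted p = 0.0418, a call lost when any of 9 arrays is left out, with adjusted p up to 0.108 without CG-1521 2) and fell with TSA (-1.38, adjusted p = 0.000858), a difference of 2.23 (adjusted p = 0.00065). ATF3, which rose with CG-1521, also rose with TSA (1.57, adjusted p = 0.000782), as did HMOX1 (0.86, adjusted p = 0.022), a call lost without vehicle 5 (0.0651), 6 (0.066) or 7 (0.0687) or TSA 1 (0.0706) and with the gradient covariate (0.0533); the rise of HMOX1 was larger with CG-1521 (difference 1.57, adjusted p = 0.00819), and that of ATF3 was not shown to differ (difference 0.49, adjusted p = 0.581).

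In the paragraphs that follow, the correlation of the TSA change with the difference between vehicle arrays, the probe order and both tests on the vehicle arrays of the 2 sets were chosen after the values they rest on had been seen; the others were written before. Other splits of the arrays within their sets were run through the same fit. For CG-1521, 2 of the 35 splits of set A gave as many called targets, the real one included (673), so chance cannot be excluded. The other split called 1896 targets and put vehicle 3 and 4 with CG-1521 1 and 2, which follows the gradient within set A and points to a structure of the arrays beside the treatment. With the gradient as a covariate, CG-1521 changed 804 targets, of which 531 were among the 673. For TSA, 4766 targets were called and the highest other of the 10 splits called 0, with too few splits for a share under 0.05. For CG-1521 against TSA, 5 of 100 splits drawn gave as many as 1265, the real one included and the highest other 6070. The other 4 all keep the TSA arrays together against their vehicle arrays, so the TSA change stays in them and they are not groupings without an effect. These splits therefore say nothing on chance for this comparison.

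The first pattern is the large number of targets that changed with TSA, with 35.9% higher in the reported fit, though 60.7% were with array weights and 64.1% with no set term. It was weighed against the gradient because the TSA arrays also lie farther along it than their vehicle arrays. With the gradient score as a covariate, the called targets kept a median share of 0.805 of their log2 fold change, with quartiles of 0.703 and 0.91. Of the 4766 calls, 2879 were kept among 3622. This argues only against a linear effect of that score as the whole cause. The score of each TSA array comes from its own levels, and the vehicle arrays of set B span only 0.47 to 0.49. The slope on the score therefore rests largely on set A, and the targets had been selected as called. A part of the change may come with the gradient, as the TSA change correlated across targets at 0.454 with the difference between vehicle 3 to 4 and vehicle 1 to 2. RNA or label integrity along the transcript stays open. The slope of probe levels along a target differed by -0.0965 between TSA and vehicle (pooled SD 0.068) with overlapping arrays. The order of the probe IDs along a transcript is not given in the files. The slope also fell with rising gradient score over vehicle 1 to 4, from 0.191 to 0.101. On CG-1521 1 it was -0.0042, against 0.129 to 0.182 on the other CG-1521 arrays. TSA 3 (0.0306) lay within the range of its vehicle arrays (-0.0087 to 0.0428). The gradient and integrity were therefore not told apart. An effect of TSA itself stays open beside them.

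The second pattern is the difference between the vehicle arrays of the sets. Quantile normalization keeps the order of probes within an array, so applying it over all arrays replaces what a separate one had set, and the 64.7% of targets that differ were counted after that step, which argues against separate quantile normalization as the whole cause. This share is the pattern's own count, and a step that changed the order of probes stays open. The gradient within set A remains a candidate explanation: the difference of set B from set A correlated across targets at 0.803 with vehicle 3 to 4 minus vehicle 1 to 2. Both differences use vehicle 1 to 4, so the shared arrays alone can give some correlation, and its size was not computed. The labels name no difference between these vehicle cultures, so no biological explanation was tested.

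The third pattern is the higher level of p53 targets after CG-1521 than after TSA. With the gradient covariate the median difference of the list was 0.601 (camera adjusted p = 5.05e-10) and without it 0.595. This argues only against a linear effect of the gradient score as the cause. Without the 3 largest members, PERP, RPS27L and CDKN1A, the camera adjusted p was 2.12e-08 and the median 0.553, which argues against a few genes deciding the list. A different effect of the 2 drugs on p53 targets may underlie it, as a hypothesis found and tested on the same data, and the doses differ. With an estimated correlation the list's adjusted p was 0.0666, and RNA integrity was not tested for this list.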
